A study of Homo sapiens with 32 samples.

How the data were processed

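The RNA sequencing part of the series was analysed, 26 of its 32 samples. These were 22 libraries of HCT116, a human colorectal cancer cell line, and 4 libraries of HEK293, a human embryonic kidney cell line. Each library came from a clonal population grown from a single sorted cell that had received Cas9-GFP. Deletion clones also received guide RNAs against a distal element named E7, 18qE or 18qNE, and control clones received the empty guide vector. Per the labels' protocols, cells were grown to near confluence, RNA was extracted with Trizol, and single-end libraries were made from 1 ug of total RNA with TruSeq v2 chemistry and sequenced on a NextSeq500. The 6 chromatin immunoprecipitation samples and the 4C interaction profiles were not analysed here.

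The values used were whole-number counts of reads per gene, as the authors deposited them, with 1 library per file and no normalization. Per the submitters' processing notes, CASAVA, bcl2fastq, TopHat2, Partek 3, HTSeq 0.6.1, BWA 0.6.2 and bedtools were used with the genome build hg19. The notes give no order of these steps, and the strand setting of the counting is not given in the sources used here. Reads of a gene and of an antisense or overlapping partner therefore cannot be told apart, which affects noncoding transcripts of the 8q24 region such as PVT1, CASC8 and CASC19, and reads shared with near-identical copies make single ribosomal protein, metallothionein and histone genes uncertain. Each HCT116 file listed 57820 genes, 51996 of which were matched to a symbol, and 5 summary lines that stayed out of library sizes and tests. Of all counted reads on days A to C (18 libraries), those summary lines held 7.78% to 14.3% outside genes, 3.03% to 3.60% in ambiguous positions and 12.3% to 13.8% aligned at several places. On day D (4 libraries), the shares were 6.34% to 7.21%, 2.86% to 3.36% and 15.6% to 24.8%. Each HEK293 file listed 11887 genes, all present in the HCT116 files, 11567 with a symbol, and no summary lines. The rule that chose those genes is not given in the sources used here, and they held 95.6% to 97.0% of the gene counts of an HCT116 library. Symbols and the order of genes along chromosomes came from NCBI tables of the assembly GRCh38.p14, which is not the build of the files, so no coordinates are given.

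Depth was the total of gene counts, 9871667 to 14862268 per library on days A to C, 22972412 to 24887785 on day D and 26491576 to 34790193 in HEK293. CPM is the usual depth-scaled count, here over the gene counts of a library alone. For genes with 1 to 3 counts in a group, the ratio of pooled CPM is given with an exact 95% interval, which covers counting error only.

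The clone was the replicate. In HCT116, 4 control clones and 1 E7 clone were each sampled on days A, B and C, and their 3 libraries were summed per clone, so that the day was balanced. The lone E7 clone is assumed to vary like the control clones. The 18qNE clones (3, with 1 library each on day A or B) were compared with the control clones summed over days A and B. The 18qE clones (2) were compared with the 2 control libraries of day D, and the 2 HEK293 E7 libraries with 2 HEK293 control libraries, all of day E. Titles number the HEK293 deletion libraries 1 and 2 while their clone label is the same, so whether they come from 1 clone or 2 is open. Where replicates are clones, p-values measure the spread between these clones. For E7 in HCT116 that spread comes from the 4 control clones alone. In HEK293 the spread of the 2 E7 libraries may be that within 1 clone.

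Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 10, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. "Rose" and "fell" are used of genes that passed it. The change from control to E7 libraries was compared between cell lines by the interaction term of one fit. Control clones were compared with each other with day as a term, days with clone as a term, and each control clone with the other 3. A set of 41 gene lists (loci, pathways, cell types and technical signs) was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Lists needed at least 5 tested members, and p was adjusted over the lists of a comparison. Counts of members "adjusted over the list alone" use the same gene p-values adjusted within the list. The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except for alternatives added later: the E7 test without day A or without block genes, the summed HEK293 libraries, the left-out libraries of the comparison between cell lines and of the HEK293 blocks and list medians, and list tests without block genes, between days, between cell lines and for 18qNE with the days matched.

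The rule for named genes took, per comparison, up to 8 genes with the largest change in each direction among those that passed the test with a mean of at least 5 CPM in the higher group and every deletion library beyond every control library. It added the neighbours of the deleted region with MYC or SMAD7 always given, and up to 4 members with the smallest p of each list that was called. Where fewer than 5 genes qualified, the 3 with the smallest p were taken.

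Extraction days pair the E7 and control libraries per the labels. Over genes, deviations from the group mean of the E7 libraries and of the control mean of the same day had correlations of 0.651, 0.362 and 0.446, and those of different days at most 0.272.

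Chromosome blocks were sought after the data had been seen, as runs of at least 10 genes in which the median log2 fold change over windows of 31 neighbouring genes with a mean of at least 5 CPM passed 0.3 in size. They were compared with 1000 shuffles of gene order. Pairs of libraries were compared by an index of difference, the chi-square over its degrees of freedom across genes with at least 20 counts, which is near 1 when only counting error separates them.

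The procedure was tested on simulated counts with 200 genes changed. At a 2-fold change it recovered 89.6% of changed genes in the E7 design of HCT116, 86.6% for 18qNE, 68.7% for 18qE, 22.4% for E7 in HEK293 and 13.4% for the interaction. At a 1.5-fold change it recovered 35.8%, 28.4%, 3%, 3% and 4.5% in the same order. Of all calls made in these simulations 19 of 169, 9 of 152, 12 of 126, 8 of 91 and 2 of 73 were of unchanged genes, a share above the 5% aimed at in each but the interaction. Simulated lists of 40 genes moved by 0.3 (log2) reached camera p, not adjusted over lists, of 0.00235, 0.000148, 0.036 and 0.0367 with an estimated correlation in the 4 deletion designs. The simulated genes were drawn independently, while real lists had estimated correlations as high as 0.838 (ribosomal proteins, E7 in HCT116) and 0.995 (the same list in HEK293). The simulation therefore does not show what this test can find in lists of correlated genes.

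Alternatives were DESeq2 1.42.0, RLE size factors in edgeR, no filter on low counts, a mean of at least 5 CPM, single libraries as replicates with and without the day or number as a block. Further ones were limma voom with the clone as a random effect, other reference groups, and leaving out each clone or library. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The result of 1 gene is not reported here.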

Results

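Transcript counts were collected from clones of 2 human cell lines that had lost a distal DNA element, E7, 18qE or 18qNE, and from clones that had received an empty guide vector. In HCT116, 12 control libraries (4 clones on each of days A, B and C), 3 E7 libraries (1 clone on the same days) and 3 18qNE libraries (3 clones) were compared, and on day D 2 control and 2 18qE libraries. In HEK293 there were 2 control and 2 E7 libraries. Gene counts per library totalled 9871667 to 14862268 on days A to C, 22972412 to 24887785 on day D and 26491576 to 34790193 in HEK293. The positions of the deleted elements are not given in the sources used here. E7 is known to belong to the 8q24 region that holds MYC, and 18qE and 18qNE to the 18q21 region that holds SMAD7.

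The first comparison asked what loss of E7 changed in HCT116, beginning with its neighbourhood. MYC (ENSG00000136997.10), a transcription factor that drives growth and division, averaged 185 CPM in the E7 libraries (SD 27.9, n = 3 libraries of 1 clone) and 420 CPM in the control libraries (SD 30.6, n = 12 libraries of 4 clones). It fell by 1.19 on the log2 scale (SE 0.11, edgeR adjusted p = 0.000733), and the highest E7 library, at 216 CPM, lay below the lowest control library, at 387 CPM. Of 18 tested genes of the 8q24 neighbourhood, MYC included, 16 fell and none rose, and 18 fell when adjusted over the list alone. TRIB1, a pseudokinase that directs protein degradation, fell by 1.52 (SE 0.15), and NSMCE2, a SUMO ligase of a DNA repair complex, fell by 1.96 (SE 0.21). SQLE, an enzyme of cholesterol synthesis, fell by 1.35 (SE 0.16), and PVT1, a long noncoding RNA, fell by 0.64 (SE 0.11). Their adjusted p ran from 0.00109 to 0.00995. Against the 18qNE clones in place of the control clones, MYC was at -1.43, TRIB1 at -1.42, NSMCE2 at -1.73, SQLE at -1.21 and PVT1 at -0.49. None of these genes passed in that test. The noncoding genes CASC8 and CASC19 had log2 changes of -0.60 and -1.35 and did not pass (adjusted p = 0.0562 and 0.0997). The list had a median of -0.97 and was called lower by camera (adjusted p = 1.78e-13; adjusted p = 0.497 with an estimated correlation). The distal part of chromosome 8 was lower as a whole, with a median of -0.58 over 171 genes from CPNE3 to C8orf33, of which 112 fell and 2 rose. The difference of MYC from that median was -0.61, and 9 genes of the block lay lower than MYC, 3 of them (NSMCE2, TRIB1 and SQLE) from the list of neighbours.

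**Figure D1:**
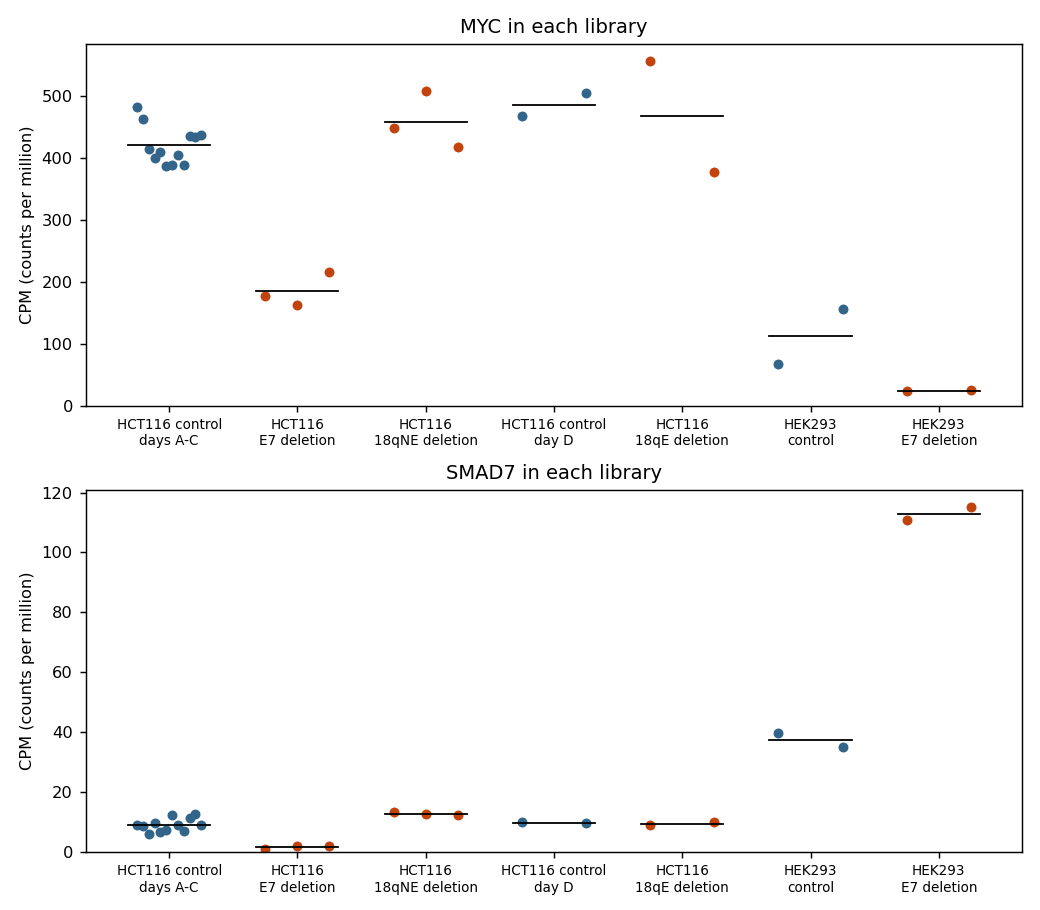
MYC and SMAD7 in CPM (counts scaled to each library's total of gene counts) in each of the 26 libraries, by group. Points are libraries, blue for control and orange for deletion, and black lines are group means. The 3 HCT116 E7 libraries hold MYC at 162 to 216 CPM, below every HCT116 control library, and the 2 HEK293 E7 libraries hold SMAD7 at 113 CPM on average against 37.4 CPM in the HEK293 controls.

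The largest changes in the E7 clone lay in genes outside the 8q24 list. APOBEC3G, a cytidine deaminase that restricts retroviruses, rose by 8.35 (SE 0.19, adjusted p = 1.67e-06), from 0.450 to 145 CPM. TM4SF18, a transmembrane protein, had 1 count in the 12 control libraries and 1748 counts in the 3 E7 libraries, a ratio of 6390 (95% counting interval 1150 to 253000). SYTL5, a vesicle trafficking protein, rose by 6.96 (SE 0.33), SEMA3A, an axon guidance cue, by 5.20 (SE 0.49), and VIM, the intermediate filament of mesenchymal cells, by 5.09 (SE 0.32). The growth factor FGF9 rose by 4.54 (SE 0.30), the microtubule-associated NAV3 by 4.43 (SE 0.48) and IGFBP3, which binds insulin-like growth factors, by 4.36 (SE 0.38). The adjusted p of these 6 genes was at most 0.00148. Against the 18qNE clones in place of the control clones, SEMA3A was at 1.75 and did not pass (adjusted p = 0.345), and FGF9 was at 2.67 and passed. ANXA10, a calcium-binding annexin of gastric epithelium, fell by 7.44 (SE 0.17, adjusted p = 1.67e-06), from 86.9 to 0.493 CPM, and the transcription factor NFIB fell by 7.57 (SE 0.27, adjusted p = 9.79e-06). DPEP1, a membrane dipeptidase that is high in many colorectal tumours, had 3648 counts in the control libraries and 2 in the E7 libraries, 499-fold lower (138 to 4120). CD33, a sialic acid receptor of myeloid cells, had 1706 and 3 counts, 155-fold lower (53.1 to 755, adjusted p = 0.0385), with control clone 4 at 1.72 CPM and the other 3 control clones at 11.5 to 17.6 CPM. CD33 had a log2 change of -7.19 in the main test. It did not pass without control clone 1 (-6.90), control clone 2 (-7.05) or the E7 library of day A (-6.54), at nearly the same size. HNF4A, a regulator of intestinal and liver genes, fell by 5.06 (SE 0.35), the retinol dehydrogenase SDR16C5 by 5.29 (SE 0.53), the adhesion receptor ICAM1 by 4.88 (SE 0.35) and the bone regulator RUNX2 by 4.71 (SE 0.81), with adjusted p of at most 0.00914. The naming rule itself required each of these genes to be beyond every one of the 12 control libraries in all 3 E7 libraries.

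By edgeR, 2456 of 17664 genes were called in the E7 clone, 1339 higher and 1117 lower, and 857 of them (437 higher, 420 lower) by at least 2-fold. Of the called genes with a mean of at least 5 CPM in the higher group, 868 higher and 617 lower genes had every E7 library beyond every control library. Chance gives this for 0.44% of all genes if the 15 libraries are exchangeable, and places 1 clone beyond 4 others for 40% of genes if clones are. With libraries as replicates and the day as a block 5178 genes were called, and without control clone 1 or control clone 2 the count was 1477 or 1499. Against the 3 18qNE clones in place of the control clones 79 of 15155 genes were called, 74 of which were among the 2456, and 49 of the 64 genes taken by the naming rule that had passed no longer did. Of these 49, 42 kept a log2 change within 1.5 times of the first, 5 were smaller (SEMA3A, TWIST1, RPL8, RPL9 and FASN) and 2 larger (LRATD2 and MT2A), and none changed sign. In that test the 18qNE libraries were of days A, B and A, and the E7 sum held days A and B only. The spread of the reference thus includes the day, by which 5773 genes differed between days A and B in the control clones.

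Among the 41 gene lists, 12 were called in the E7 clone at the preset correlation, and none with an estimated correlation, where the lowest adjusted p was 0.497. The median of all tested genes was -0.01. Of 43 tested MYC targets 12 fell and 1 rose (14 and 2 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.000343; adjusted p = 0.754 with an estimated correlation). NOLC1, a nucleolar chaperone, fell by 0.76, RRP9, a factor of ribosomal RNA processing, by 0.47, and CAD, which starts pyrimidine synthesis, by 0.39, while PLK4, a kinase of centriole duplication, rose by 0.46. Of 60 ribosome biogenesis genes 11 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.17 (adjusted p = 1.36e-06; adjusted p = 0.746 with an estimated correlation). RRP1B fell by 0.47 and the methyltransferase FBL by 0.50. The 2 that rose, NOP2 (0.41) and the RNA helicase DDX47 (0.84, picked after its value was seen), lie at the start of chromosome 12, which was higher as a block. Genes of DNA replication and E2F were not called (49 genes, median -0.06, adjusted p = 0.225; adjusted p = 0.861 with an estimated correlation). Of 74 ribosomal protein genes 3 fell (2 adjusted over the list alone), RPL8 by 0.71, RPL30 by 0.63 and RPL9 by 0.33, and RPL8 and RPL30 lie in the lower block of chromosome 8. The list median was -0.17 (adjusted p = 1.36e-06; adjusted p = 0.853 with an estimated correlation). Of 44 genes of mitosis 11 rose and none fell, also when adjusted over the list alone, with a median of 0.19 (adjusted p = 1.6e-05; adjusted p = 0.746 with an estimated correlation). CDC25C, a phosphatase that starts mitosis, rose by 0.70 and the cyclin CCNB2 by 0.45, and CDCA3 and FOXM1, both in the higher block of chromosome 12, rose by 0.63 and 0.51. CAD did not pass without control clone 2 (-0.378), nor FBL without control clone 1 (-0.458) or 2 (-0.516), at log2 changes near those of the main test. RPL9 did not pass without control clone 1 (-0.318) or 2 (-0.356), the E7 library of day A (-0.32) or C (-0.322), or day A in both groups (-0.267). Without the E7 library of day B, CCNB2 was at 0.27 and did not pass (adjusted p = 0.0504) and CDCA3 was at 0.38 and passed. Without the genes of both blocks the mitosis list had a median of 0.18 (adjusted p = 0.000111; adjusted p = 0.779 with an estimated correlation).

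Of 21 mesenchymal genes 7 rose and 2 fell in the E7 clone (7 and 3 adjusted over the list alone), with a median of 0.91 (adjusted p = 0.0488; adjusted p = 0.746 with an estimated correlation). Besides VIM, the transcription factor TWIST1 rose by 4.34 (SE 0.38; 2.50 against the 18qNE clones, adjusted p = 0.364) and the receptor kinase AXL by 2.00 (SE 0.13), while TAGLN, an actin-binding protein, fell by 2.31 (SE 0.18) and the transcription factor SNAI1, picked after its value was seen, by 0.67. The list of 34 epithelial junction genes was not called (median -0.14, adjusted p = 0.0981; adjusted p = 0.846 with an estimated correlation). Of its members CLDN2 and KRT19 rose, and OVOL1, the cadherin CDH1 and AP1M2 fell, all picked after their values were seen. Of 7 enterocyte genes 1 fell, HNF4A (4 adjusted over the list alone), with a median of -0.45 (adjusted p = 0.0496; adjusted p = 0.731 with an estimated correlation). Of 10 tested markers of HEK293 cells 2 fell, DPYSL3 and GATA3, and none rose. Of 11 leukocyte markers LYZ rose and CD8A fell, all 4 genes being picked after their values were seen, and none of 8 neuronal and 6 endothelial markers passed. Of 13 mitochondrially encoded genes 4 fell (7 adjusted over the list alone), MT-CO2 by 0.66, MT-ND4 by 0.63 and MT-CO3 and MT-ATP6 by 0.51 each. Their list had a median of -0.43 (adjusted p = 0.000455; adjusted p = 0.746 with an estimated correlation). Mitochondrial mRNA made up 3.64% to 4.32% of counts in the E7 libraries and 4.71% to 6.60% in the control libraries. Of 20 genes of fatty acid synthesis 4 fell, also when adjusted over the list alone: ACSL1, which activates fatty acids, by 1.17, ME1 by 0.65, the elongase ELOVL6 by 0.59 and the fatty acid synthase FASN by 0.37. Their list had a median of -0.13 (list adjusted p = 0.0496; adjusted p = 0.754 with an estimated correlation). Of 5 metallothioneins 2 rose (3 adjusted over the list alone), MT2A by 0.94 and MT1X by 0.90 (list adjusted p = 0.0496; adjusted p = 0.731 with an estimated correlation). Of 23 genes of the unfolded protein response 3 rose, also when adjusted over the list alone, CREB3L2 by 0.51, DNAJC3 by 0.32 and HYOU1 by 0.30 (list adjusted p = 0.0488; adjusted p = 0.731 with an estimated correlation). Of 30 proteasome subunits 2 fell (1 adjusted over the list alone), PSMC5 by 0.61 and PSMA2 by 0.39 (list adjusted p = 0.0496; adjusted p = 0.861 with an estimated correlation). Several of these calls were lost when single clones or libraries were left out, and leaving out control clones changed the log2 changes little. Without control clone 1, MT-ND4 (-0.65), ELOVL6 (-0.604), MT2A (0.945), DNAJC3 (0.305), HYOU1 (0.322) and PSMA2 (-0.368) did not pass. Without control clone 2, MT-ND4 (-0.615), ELOVL6 (-0.58), FASN (-0.38), DNAJC3 (0.336), HYOU1 (0.304) and PSMA2 (-0.4) did not. Without control clone 4, DNAJC3 (0.304), HYOU1 (0.281) and PSMA2 (-0.377) did not. Without the E7 library of day A, CREB3L2 (0.17), DNAJC3 (0.14), HYOU1 and PSMA2 did not pass, without that of day B ELOVL6 and FASN (-0.27), and without that of day C ELOVL6 and PSMA2. Without day A in both groups MT1X, MT2A, CREB3L2 (0.31), DNAJC3 (0.17) and HYOU1 (0.20) did not pass, and FASN was at -0.08 against the 18qNE clones. TGF-beta and SMAD target genes went both ways, with 6 of 27 higher and 5 lower (7 and 9 adjusted over the list alone). SMAD7, an inhibitor of TGF-beta signalling, fell by 2.49 (adjusted p = 0.00127), and the matrix protein CCN2, picked after its value was seen, rose by 3.03. This list was not called by camera.

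**Figure D2:**
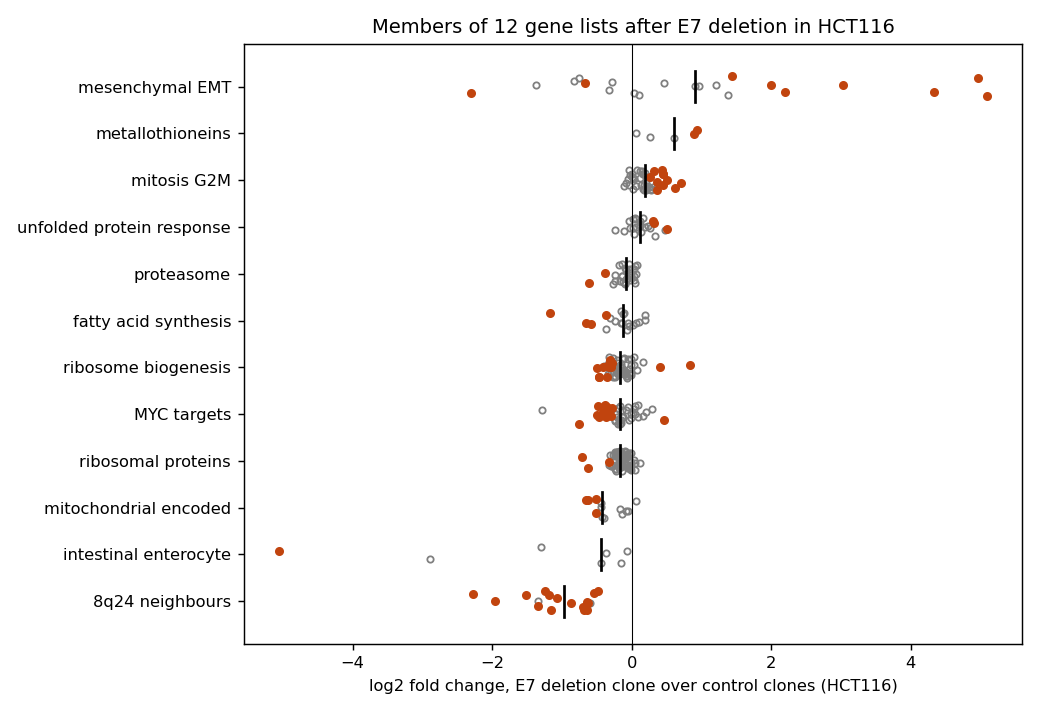
Log2 fold change of each tested member of the 12 gene lists called in the HCT116 E7 clone against the control clones. Filled orange points passed the test over all genes, open points did not, and black lines are list medians, which run from -0.97 for the 8q24 neighbours to 0.91 for the mesenchymal list.

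Along the chromosomes, the E7 clone of HCT116 had 2 blocks of genes that were shifted together. In addition to the lower block of distal chromosome 8, 118 genes at the start of chromosome 12, from KDM5A to AMN1, had a median of 0.61, and 90 of them rose and 1 fell. The highest window of 31 genes reached a median of 0.743, and at most 0.348 in 1000 shuffles of gene order. The chromosome 8 block stood at -0.618, -0.533 and -0.532 in the 3 E7 libraries and the chromosome 12 block at 0.583, 0.645 and 0.602, and no single control clone had such a block. Of the called genes with a chromosome position, 246 of 2340 lay in the blocks, and without block genes 2127 of 17136 genes were called (1169 higher, 958 lower).

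**Figure D3:**
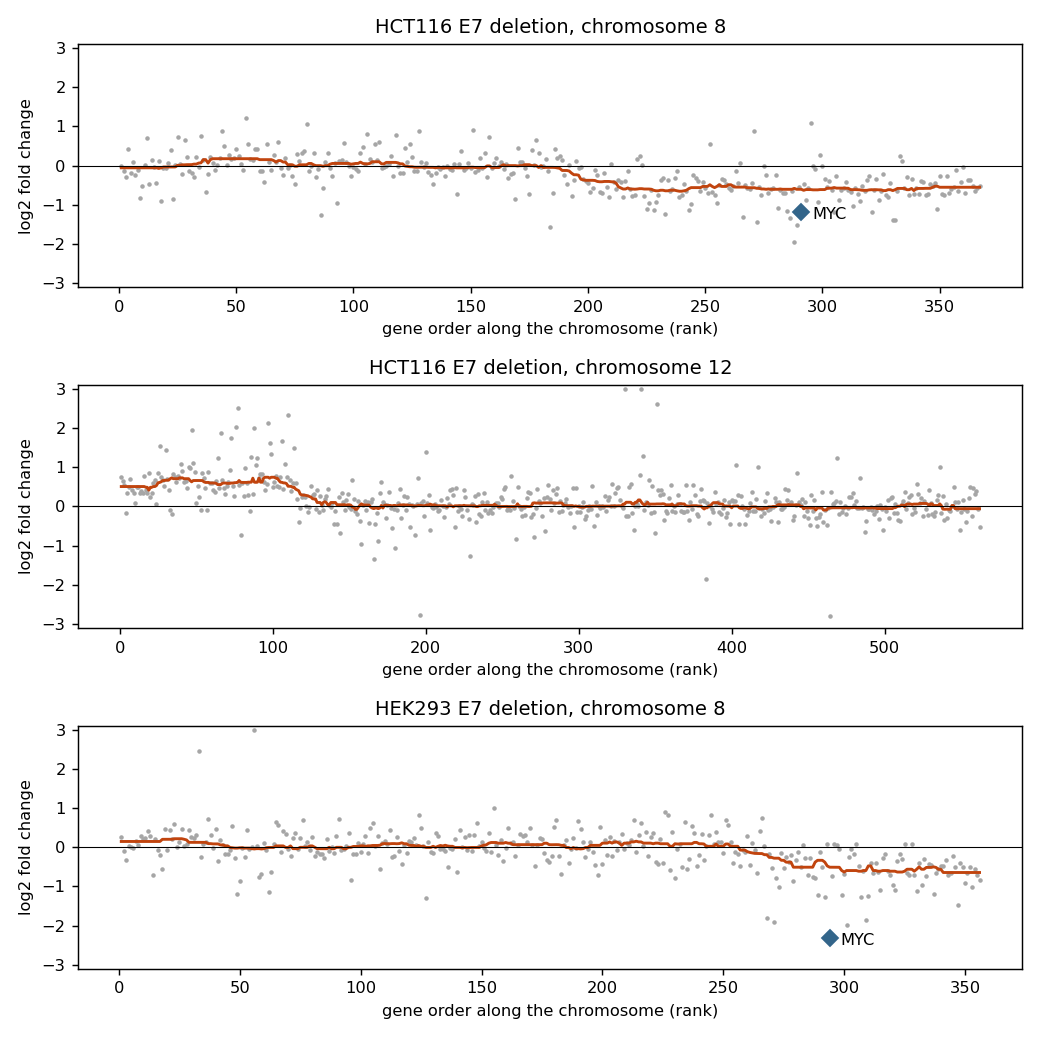
Log2 fold change (clipped at 3 in either direction) against gene order along chromosomes 8 and 12 after E7 deletion in HCT116 and along chromosome 8 in HEK293. Grey points are genes, the orange line is the median over windows of 31 genes and the blue diamond is MYC; the distal part of chromosome 8 lies below 0 in both cell lines and the start of chromosome 12 above 0 in HCT116.

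The same deletion in HEK293 asked whether the effects depend on the cell line. MYC was at 23.3 and 24.5 CPM in the E7 libraries and at 67.4 and 156 CPM in the control libraries, a log2 change of -2.31 (SE 0.45, n = 2 and 2) that did not pass (adjusted p = 0.222). It passed by DESeq2, and over the 10 alternatives its log2 change ran from -2.82 (without control 1) to -1.52 (without control 2). Leaving out any of the 4 libraries leaves 1 library in a group, so only the size of the change is given there. Without control 1 or 2 the SE was 0.111 or 0.119, because the spread then came from the 2 E7 libraries alone, which may be 1 clone. PKP3, a plakophilin of cell junctions, fell by 7.68 (SE 0.31, adjusted p = 0.0125), from 45.1 to 0.228 CPM, and MAOA, which breaks down monoamine transmitters, fell by 3.28 (SE 0.21, adjusted p = 0.0492). NEFM, a neurofilament subunit, rose by 5.54 (SE 0.28, adjusted p = 0.0198), from 0.656 to 32.2 CPM. These 3 were the genes called by edgeR among 11806, with both E7 libraries beyond both control libraries, which chance gives for 33.3% of genes if the 4 libraries are exchangeable. At an unadjusted p below 0.05 there were 1487 genes, and DESeq2 called 463. The count depended on single libraries: it was 6210 without control 1, 1914 without control 2, 74 without E7 library 1 and 77 without E7 library 2, and with both E7 libraries summed as 1 clone it was 71.

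Of 12 tested 8q24 neighbours in HEK293, MYC included, none passed over all genes, and MYC, TRIB1 (log2 change -1.26) and SQLE (-1.21) were lower adjusted over the list alone. Their median was -0.72 (adjusted p = 0.000649; adjusted p = 0.701 with an estimated correlation), and 83 genes of distal chromosome 8, from MTBP to C8orf33, had a median of -0.52, which was -0.23 without control 2 and -0.80 without control 1. At the preset correlation 19 of 35 lists were called, and none with an estimated correlation, where the adjusted p of each of the 19 was 0.701. Interferon response genes had the largest list median, 0.92 over 21 genes (adjusted p = 7.74e-08; adjusted p = 0.701 with an estimated correlation). None of them passed over all genes, and 9 were higher and 1 lower adjusted over the list alone, such as IFI6 (3.09, SE 0.35) and IFITM2 (-1.05). TGF-beta and SMAD targets had a median of 0.43 over 24 genes (adjusted p = 0.00417), with 9 higher and 2 lower adjusted over the list alone. CCN2 (2.82) and PMEPA1 (2.06) were among the higher, and the lower were ID3 (-2.26) and ID1 (-2.25). IFITM2, ID3 and ID1 were picked after their values were seen. After the 8q24 neighbours, the lowest medians belonged to ribosomal proteins (74 genes, -0.59, adjusted p = 7e-09), histones of replication (11 genes, -0.44, adjusted p = 0.00854) and ATF4 targets (27 genes, -0.40, adjusted p = 0.00208). Lower too were oxidative phosphorylation (65 genes, -0.38, adjusted p = 1.01e-05), p53 targets (29 genes, -0.38, adjusted p = 6.73e-05, 6 lower adjusted over the list alone) and MYC targets (44 genes, -0.36, adjusted p = 0.000155). Glycolysis, cholesterol synthesis, hypoxia, ribosome biogenesis, heat shock and E2F lists were called lower too, with medians of -0.26, -0.23, -0.22, -0.20, -0.18 and -0.16. HOX genes (0.31), intestinal stem cell markers (0.33) and neuronal markers (0.37, with NEFM as the 1 gene of 5 that rose) were called higher. Epithelial junction genes were called higher with a median of 0.40, although their mean, which includes the fall of PKP3, was -0.042. All 466 genes of chromosome 16 in the profile, RPS2, RPL13 and ALDOA among them, formed 1 lower block with a median of -0.63 (-0.62 and -0.66 without control 1 and 2). On chromosome 20, 245 and 40 genes formed 2 more with medians of -0.50 and -0.36 (-0.32 and -0.22 without control 2, -0.61 and -0.57 without control 1). In all there were 15 blocks, with smaller lower ones on chromosome 6 (-0.38 and -0.34; -0.09 and -0.06 without control 1) and higher ones on chromosomes 7, 9 and 17. The highest window median in HEK293 was 1.037 in size, and at most 0.482 in 1000 shuffles of gene order. Windows past the cut of 0.3 thus also arose in shuffled order. The blocks on chromosomes 6, 7, 9 and 17 and the smaller one on chromosome 20 had medians below 0.482 in size. They are not shown to be regional shifts. The 5 higher blocks of chromosome 7 had medians of 0.27 to 0.39, which were -0.01 to 0.29 without control 1 and 0.49 to 0.60 without control 2, and 1 block there of 12 genes had no clear direction (-0.07; -0.34 without control 1 and 0.63 without control 2). Chromosome 9 held 1 block (0.39; 0.25 without control 1) and chromosome 17 held 2 (0.40 and 0.29; 0.87 and 0.46 without control 1, 0.09 and 0.12 without control 2).

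The lower list medians in HEK293 also leaned on control 2. Without it, ribosomal proteins had a median of 0.00, oxidative phosphorylation 0.03, glycolysis -0.01, ribosome biogenesis -0.02, ATF4 targets -0.04, MYC targets -0.08, E2F genes -0.07, cholesterol synthesis -0.13, hypoxia genes -0.15 and the 8q24 neighbours -0.31. Interferon response (0.84), TGF-beta and SMAD targets (0.48), p53 targets (-0.45) and neuronal markers (0.38) stayed within 1.5 times of their medians when control 2 was left out, and replication histones were at -0.77. Without control 1, ribosomal proteins were at -1.01, replication histones at -0.15, HOX genes at 0.12 and TGF-beta and SMAD targets at 0.65. Cholesterol synthesis was at -0.10 and -0.52 without E7 library 1 and 2.

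Whether the change from control to E7 libraries differed between the cell lines was tested directly, with 1 E7 clone on the side of HCT116. SMAD7 (ENSG00000101665.4) was at 1.64 CPM after E7 deletion and 8.99 CPM in controls of HCT116, and at 113 and 37.4 CPM in HEK293 (log2 change 1.53, SE 0.18, adjusted p = 0.143), and its log2 change differed by -4.04 (SE 0.29, adjusted p = 0.000839). The log2 change was also lower in HCT116 for NFIB (-7.96, adjusted p = 1.46e-05), and higher for PKP3 (7.48, adjusted p = 1.46e-05) and SYTL5 (6.21, adjusted p = 0.00254). It was higher too for VIM (5.07, adjusted p = 0.00134), FGF9 (5.01, adjusted p = 0.00271), SEMA3A (4.54, adjusted p = 0.0294) and MAOA (3.06, adjusted p = 0.000621). For MYC the difference was 1.10 (SE 0.49) and did not pass (adjusted p = 0.272). In all, 401 of 11849 genes had a different change, 229 higher and 172 lower in HCT116. That count was 92, 97, 182 and 171 without each HCT116 control clone in turn, 4701 and 2081 without HEK293 control 1 and 2, and 35 and 39 without HEK293 E7 library 1 and 2.

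Deletion of 18qNE in HCT116 asked what loss of that 18q element changed. SMAD7 averaged 12.8 CPM in the 18qNE clones (SD 0.398, n = 3) and 9.94 CPM in the control clones summed over days A and B (SD 1.74, n = 4). Its log2 change of 0.38 (SE 0.16) did not pass (adjusted p = 1), and none of 24 tested 18q21 neighbours passed, over all genes or adjusted over the list alone. The smallest p belonged to SLC2A1, the main glucose transporter, with a log2 change of 0.97 (SE 0.12, adjusted p = 0.136) from 344 to 663 CPM. Next were DNAH2, a dynein of cilia (-2.93, SE 0.41), and CASP10, a caspase that starts apoptosis (-1.45, SE 0.21), with an adjusted p of 0.234 for both. edgeR called 0 of 15524 genes, with 505 at an unadjusted p below 0.05, and DESeq2 called 13. With single libraries as replicates, several of them from the same control clone, and the day as a block 3 genes were called, SLC2A1, DNAH2 and SEMA3A. With the same block and the clone as a random effect only SLC2A1 was called, and without 18qNE clone 2 there was 1, SLC2A1. SEMA3A and FGF9, which rose in the E7 clone, had log2 changes of 3.49 (SE 0.55) and 1.82 (SE 0.32) in the main 18qNE test and did not pass (adjusted p = 0.344 and 0.605).

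At the preset correlation 12 of 39 lists were called after 18qNE deletion, none of them with an estimated correlation, and no member passed over all genes. Ribosomal protein genes were lower (74 genes, median -0.18, adjusted p = 3.46e-23; adjusted p = 0.659 with an estimated correlation), as were genes of oxidative phosphorylation (65 genes, -0.08, adjusted p = 1.23e-06; adjusted p = 0.707 with an estimated correlation). Hypoxia genes were higher (28 genes, median 0.31, adjusted p = 1.23e-06; adjusted p = 0.659 with an estimated correlation), as were glycolysis genes (20 genes, 0.11, adjusted p = 0.000343; adjusted p = 0.659 with an estimated correlation). SLC2A1 was the 1 gene of either list that was higher adjusted over the list alone. Wnt targets (19 genes, median 0.11, adjusted p = 0.0461; adjusted p = 0.644 with an estimated correlation) had 1 such gene, FGF9, at 1.82. Metallothioneins (-0.44), replication histones (-0.34) and p53 targets (-0.04) were called lower, and immediate early (0.21), HOX (0.15), NF-kB (0.15) and epithelial junction genes (0.13) higher, with adjusted p from 0.00624 to 0.0461 and from 0.644 to 0.933 with an estimated correlation. The main test had no day term, and 2 of the 3 18qNE libraries were of day A. With single libraries and the day as a block 7 of the 12 lists were called in the same direction, and on day A alone 7. The median of p53 targets was larger in size in both, -0.105 with the block and -0.128 on day A. That of ribosomal proteins was -0.208 with the block and -0.113 on day A. Metallothioneins (median -0.26 with the block, adjusted p = 0.189, and -0.01 on day A, adjusted p = 0.734), immediate early genes, NF-kB and Wnt targets were called in neither, HOX genes not with the block and epithelial junction genes not on day A. No list was called in either with an estimated correlation.

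Deletion of 18qE in HCT116, compared within day D, asked the same of the other 18q element. SMAD7 was at 9.38 CPM (SD 0.822, n = 2 clones) after deletion and at 9.76 CPM (SD 0.261, n = 2) in the controls, a log2 change of -0.03 (SE 0.22, adjusted p = 1). None of 23 tested 18q21 neighbours passed, over all genes or adjusted over the list alone. The smallest p belonged to GFY, a Golgi protein of olfactory neurons (2.55, SE 0.36), KRT6A, a keratin of stressed epithelia (1.98, SE 0.27), and ZNF608, a zinc finger protein (2.38, SE 0.37), each with an adjusted p of 1. edgeR called 0 of 15261 genes, with 391 at an unadjusted p below 0.05, and DESeq2 called 19. Without 18qE clone 1 the count was 107, without 18qE clone 2 it was 132, and without control clone 1 it was 1, PRPS1, an enzyme of nucleotide synthesis picked after its value was seen.

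Hypoxia genes stood out after 18qE deletion. All 28 tested members had a positive log2 change, with a median of 0.61 (adjusted p = 3.11e-13; adjusted p = 0.577 with an estimated correlation). None passed over all genes, and 5 were higher adjusted over the list alone: SLC2A3 (1.52), DDIT4 (1.47), NDRG1 (1.16), SLC2A1 (0.61) and, picked after its value was seen, VEGFA (0.61). Over the alternatives DDIT4 ran from 0.886 to 1.88, NDRG1 from 0.898 to 1.49, SLC2A3 from 1.35 to 1.71 and SLC2A1 from 0.559 to 0.655. At the preset correlation 11 of 39 lists were called, and the estimated correlation gave each of the others below an adjusted p of 0.577 except where stated. Epithelial junction genes (34 genes, 0.21, adjusted p = 2.09e-07) and glycolysis genes (20 genes, 0.19, adjusted p = 1.3e-06) were called higher. So were immediate early genes (29 genes, 0.22, adjusted p = 0.000786; adjusted p = 0.638 with an estimated correlation) and ribosomal proteins (74 genes, 0.09, adjusted p = 0.00234; adjusted p = 0.996 with an estimated correlation). The unfolded protein response (0.12), leukocyte markers (0.25) and Notch genes (0.20) were called higher too, and replication histones (-0.31) and metallothioneins (-0.45) lower, with adjusted p from 0.00503 to 0.0378. Mesenchymal genes were called lower (16 genes, median -0.04, mean -0.387, adjusted p = 0.00617), with VIM (-3.37), TAGLN (-1.59) and S100A4 (-0.70) lower adjusted over the list alone. Over the alternatives VIM ran from -5.24 to -2.25, TAGLN from -1.93 to -1.28 and S100A4 from -0.887 to -0.495. VIM was near the floor in HCT116 without a deletion, at 0.410 to 1.10 CPM in the control clones summed over days A to C. Its large log2 change can therefore rest on few reads and does not show loss of a well expressed marker.

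Differences among clones without a deletion give the background for these counts. Across the 12 control libraries with day as a term, 1169 of 14988 genes differed between the 4 control clones, led by TPBG, an oncofetal membrane protein, and TM9SF3, a Golgi membrane protein (adjusted p = 6.71e-11 for each). Tested like the E7 clone, control clones 1, 2, 3 and 4 gave 0, 0, 111 and 9 called genes against the other 3, with 291, 227, 1796 and 1220 at an unadjusted p below 0.05. The E7 clone against the same 3 gave 1477, 1499, 3087 and 2608. The extraction day had a wider effect: 5731 of 14988 genes differed between days, with 5773 between days A and B, 4831 between A and C, and 5 between B and C, picked after their values were seen: SRSF2, FJX1, SAMD11, LINC00641 and a gene without a symbol. Without day A the E7 clone had 1878 called genes.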

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

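The comparison of called genes with the chromosome blocks, the place of MYC within its block, and the left-out libraries of the comparison between cell lines and of the HEK293 blocks were chosen only after the result was seen.

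The change from control to E7 libraries differed between HCT116, with 1 E7 clone, and HEK293 for 401 genes by the test of the difference itself, a count that was 4701 and 2081 without HEK293 control 1 and 2 and 35 and 39 without HEK293 E7 library 1 and 2. Leaving out each HCT116 control clone in turn gave 92, 97, 182 and 171. As log2 differences, HCT116 minus HEK293, this drew attention to SMAD7 (-4.04), NFIB (-7.96), PKP3 (7.48), SYTL5 (6.21), VIM (5.07), FGF9 (5.01), SEMA3A (4.54) and MAOA (3.06). TM4SF18 was at 0.0274 CPM in control clone 1 and at 0 in the other 3 control clones, flagged as far apart relative to the range, with 28 measures checked. It rests on 1 count. Any gene counted in only 1 control clone is flagged by this rule, so the flag says nothing about that clone.

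The single E7 clone of HCT116 had 2456 called genes, and ordinary spread between clones, block dosage and a shared E7 effect were weighed. Against the 4 control libraries of the same day, single 18qNE clones called at most 2 genes (2, 1 and 0) while the E7 library called 673 on day A and 965 on day B, which argues against ordinary spread, although control clone 3 called 111 against the other 3, and the E7 clone called only 79 of 15155 against the 3 18qNE clones, where 49 of 64 named genes lost the call, 42 of them with a log2 change within 1.5 times of the first. The test against the 18qNE clones mixed days A and B in those clones and lacked the E7 library of day C, so the day was not balanced. The blocks of chromosomes 8 and 12 held 10.5% of the called genes with a position and 2.9% of the tested ones. Inside the blocks 53.5% of genes were called, and outside 13.8%. Most calls thus lay outside the blocks, which argues against the dosage of the called genes themselves as the whole cause. Whether block genes changed genes elsewhere was not tested, so dosage acting through them stays open. Outside the distal chromosome 8 block, 61.6% of 1607 genes called in HCT116 had the same sign in HEK293, past the 60% set before this count, against 55.6% among 9553 uncalled genes. The block left out was itself found after the data had been seen, and the chromosome 12 block stayed in. The signs were not recounted without single HEK293 libraries. Part of the pattern may be an effect that both lines share, though genes are not independent replicates. With 1 E7 clone in HCT116, an effect of the deletion and properties of that clone cannot be separated by this design, and both stay open.

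MYC and its 8q24 neighbours were lower after E7 deletion, inside blocks of lower genes, and gene dosage of the block and an effect on the locus itself are the candidate explanations. A change from 3 copies to 2 would give -0.585, close to the block median of -0.575 in HCT116, and copy number was not analysed here. MYC lay -0.613 from that median, with 9 block genes lower, 3 of which are neighbours that a local effect would lower as well. Among the 158 block genes outside the list of neighbours 6 were lower, and MYC lay -0.062 from their 5th percentile (-1.126), less than its SE of 0.106. In HEK293 MYC lay -1.051 from the 5th percentile of the block (-1.06 without the neighbours), more than 2 times its SE of 0.45, and none of 83 block genes was lower, which argues against block dosage as the whole cause for MYC in that line. There its change of -2.31 did not pass the test over all genes. The block itself leaned on control 2, with a median of -0.516, and -0.229 without that library; MYC was then at -1.524 (SE 0.119), -0.64 from the 5th percentile, with 1 block gene lower. Without E7 library 1 or 2 MYC lay -0.878 and -0.922 from it, less than 2 times the SE of 0.573 and 0.575. The 12 neighbours with a place in the block, MYC left out, lay -0.224 from the rest in HCT116. Of 10000 random sets of block genes 0.35% were as low, against 8.62% in HEK293. These sets were scattered over the block, while the neighbours belong to 1 locus. If genes close together move together, stretches as low would be more frequent than these shares. Both limits set before this test, on the difference (0.2) and on the random sets, were passed in HCT116. By that rule the result goes against block dosage as the whole cause for the neighbours. The difference passed 0.2 by less than its bootstrap SD of 0.186, a margin that was not part of the rule. So for MYC in HCT116, block dosage as the whole cause cannot be told apart from an added local effect. There 6 block genes outside the list lay lower than MYC, and its margin past the 5th percentile is smaller than its SE. For the neighbours the rule was met, but the small margin past 0.2 keeps both explanations open. Whether MYC fell beyond its block in HEK293 stays uncertain, since the margin was under 2 times its SE without either E7 library. What could lower it further was not tested.

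The 2 HEK293 deletion libraries were nearly alike (correlation 0.9935 over genes) and the 2 control libraries were not (0.9453), and 1 library deposited under 2 names and block dosage were weighed. The index of difference of the deletion libraries was 19, where counting error alone gives 1, which argues against 1 library counted a second time; the control pair had 210. Outside the blocks that differed between the control libraries, the index of the controls was still 10.9 times that of the deletion libraries (173 and 15.8). Shuffled gene order reached window medians of up to 0.745 in this pair, past the cut of 0.3, so the border of these blocks is uncertain. This argues against direct dosage of the genes in those blocks as the whole cause. Shifts too small to form a block and effects of block genes on genes elsewhere were not tested, and copy number was not analysed here. That both deletion libraries are 1 clone, as their shared clone label reads, and that control clones differ by more than dosage, remain possible and untested, and no biological explanation was tested.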

How the results depend on the processing

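The E7 calls without day A, without block genes and with the summed HEK293 libraries, the left-out libraries of the interaction, the HEK293 blocks and list medians with libraries left out, and the 18qNE lists with days matched, were chosen after seeing the data. No named gene reversed its direction while called. The E7 count in HCT116 stayed within 1.5 times of 2456 with DESeq2, RLE factors, no filter, a mean of 5 CPM, single libraries without a block, each E7 day left out and day A left out. It moved to 5178 with the day as a block, 4003 with limma voom, day as a block and clone as a random effect, 79 against the 18qNE clones (cause not tested) and 857 at a 2-fold change, and ran from 1477 to 3087 when single clones were left out. Of 64 named genes that passed, 47 did so in every setting except the 18qNE reference, where 49 lost the call, 42 of them at a log2 change within 1.5 times. That reference mixed days A and B and lacked the E7 library of day C. The 18qNE count of 0 became 13 with DESeq2, 16 without a filter, 1 with single libraries and no block, 3 with the day as a block and 1 with limma voom and the block, and ran from 0 to 1 when clones were left out. The 18qE count of 0 became 19 with DESeq2 and ran from 0 to 132. The HEK293 count of 3 became 463 with DESeq2 and 71 with the E7 libraries summed, and ran from 74 to 6210; its 3 genes were called in each setting. The interaction count of 401 became 1175 with DESeq2 and ran from 35 to 4701, and the control clone count of 1169 became 1959 without a filter (more genes tested). Where no construction is named, the cause was not tested. With an estimated correlation the counts of called lists went from 12, 12, 11 and 19 (E7, 18qNE, 18qE, HEK293 E7) to 0. Numbers shared by 18qE clones and day D controls, and by HEK293 libraries, do not pair samples in the labels: correlations of same-numbered deviations were 0.044 and 0.327, and the number as a block called 0 and 670 genes. The 18qNE lists went from 12 to 9 with the day as a block and 13 on day A only, with 7 of the 12 called in each. Weak changes were out of reach in some designs: the simulated HEK293 and 18qE designs recovered 3% of genes changed 1.5-fold and the E7 design of HCT116, with 3 libraries summed per clone, 35.8%. Depth and the number and spread of replicates differ together between these designs, so what depth limits was not tested apart.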

Other observations

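The gene lists of the extraction days were tested only after the result was seen; the splits of the samples were planned.

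Control clones differed most between day A and days B and C, and the lists describe that difference. Lower on day A were mitosis (44 genes, median -0.51, camera adjusted p = 1.71e-17) and ribosome biogenesis (60 genes, -0.42, adjusted p = 5.76e-21). So were MYC targets (43 genes, -0.41, adjusted p = 2.19e-15), E2F targets (49 genes, -0.33, adjusted p = 6.3e-13) and DNA repair genes (36 genes, -0.25, adjusted p = 4.72e-06), and each of these 5 lists had an adjusted p of 0.319 with an estimated correlation. Proteasome subunits (30 genes, -0.29, adjusted p = 1.28e-07) and heat shock genes (17 genes, -0.33, adjusted p = 0.000328) were lower as well, with an adjusted p of 0.443 for both with an estimated correlation. Metallothioneins had the lowest median, -1.12 over 5 genes (adjusted p = 0.00748; adjusted p = 0.319 with an estimated correlation).

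Lists of p53 targets (30 genes, 0.29), TGF-beta and SMAD targets (27 genes, 0.33), cholesterol synthesis (25 genes, 0.28), immediate early genes (29 genes, 0.33) and interferon response (32 genes, 0.28) were higher on day A, with adjusted p from 3.22e-05 to 0.00197 and of 0.319 for each with an estimated correlation. Ribosomal proteins (74 genes, 0.12, adjusted p = 0.0023; adjusted p = 0.754 with an estimated correlation) and mitochondrially encoded genes (13 genes, 0.305, adjusted p = 0.00748; adjusted p = 0.319 with an estimated correlation) were higher too. So were Wnt targets (19 genes, 0.24, adjusted p = 0.00357; adjusted p = 0.345 with an estimated correlation) and class I MHC genes (14 genes, 0.24, adjusted p = 0.0405; adjusted p = 0.443 with an estimated correlation). In all 17 of 39 lists were called between the days at the preset correlation and none with an estimated one. The change from control to E7 libraries differed between cell lines, HCT116 minus HEK293, for 7 of 35 lists at the preset correlation. Interferon response (-0.98, adjusted p = 2.08e-07; adjusted p = 0.136 with an estimated correlation) and TGF-beta and SMAD targets (-0.29, adjusted p = 0.00192) were lower in HCT116. Higher there were p53 targets (0.39), glycolysis (0.38), ATF4 targets (0.35), ribosomal proteins (0.32) and oxidative phosphorylation (0.30), with adjusted p from 0.00192 to 0.0467, and from 0.635 to 0.86 for these 5 and the TGF-beta list with an estimated correlation. In HEK293 alone, ribosomal proteins, oxidative phosphorylation, glycolysis and ATF4 targets had medians within 0.05 of 0 without control 2.

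Other chromosome blocks were seen. After 18qE deletion, 18 genes of chromosome 1, from CEP170 to PGBD2, had a median of 0.49, and none of them passed the test. Between the 2 HEK293 control libraries, 85 blocks held 31.6% of genes in the profile, and between the 2 HEK293 deletion libraries there was none. For the control pair the highest window median was 0.893 in size, and at most 0.745 in 1000 shuffles of gene order. Windows past the cut of 0.3 thus also arose in shuffled order, and most of the 85 blocks are not shown to be regional shifts. The distal chromosome 8 genes stood at -0.014 and 0.581 in HEK293 controls 1 and 2 and at -0.249 and -0.248 in the deletion libraries. Chromosome 16 genes stood at 0.322 and 0.334 in the controls and at -0.331 and -0.298 in the deletion libraries.

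Other splits of the same samples were counted. For 18qNE the real count was 0, which all 35 splits of the 7 clones reach whatever they call, so the splits decide nothing there; the highest other split called 1. For the control clones, 1 of 100 splits with clone names shuffled within each day, the real one, reached 1169, and the highest other called 290. This argues against chance, although 100 splits cannot show a share below 1 in 100. For the days, 1 of 100 splits, the real one, reached 5731, and the highest other called 4660. The 4 splits that kept the libraries of day A together called 4022 to 4660 and the other 95 at most 4, which points to day A as the structure behind the count.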
